A study of Homo sapiens with 6 samples.

How the data were processed

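RNA was measured in OCI-Ly10, a human diffuse large B-cell lymphoma line, by strand-specific sequencing of total RNA depleted of ribosomal RNA, per the labels' protocols. The labels give 6 samples, 1 for each of DMSO, 75 nM CU-O75 and 750 nM CU-O75 at 12 h and 24 h. Each sample was placed in its group by its title. The tables used here have columns for 4 of these samples, the 2 doses at the 2 times. The 2 DMSO samples were not analysed here. The submitters' processing notes name STAR, DESeq2, limma and the build GRCh38, with no versions and no roles.

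For each time the authors deposited 1 table of 25559 gene symbols. Its signal columns hold, per the file headers, the mean normalized count of each dose over a pair of libraries, and the deposited values are read counts divided by a size factor per library. The deposited fold column is the ratio of the 750 nM mean to the 75 nM mean, per the file headers and checked against the means. The p-value and adjusted p-value columns are the authors' own test of the 2 doses, per the file headers, whose column names are those of the DESeq family of packages. The deposited log2 column was damaged by a spreadsheet, so log2 fold changes were computed from the deposited fold. At each time 26 symbols had been turned into dates and stayed without a name. Among genes with a p, the log2 fold change was not finite for 1690 at 12 h and 1683 at 24 h because 1 of the doses was at 0. The authors also deposited 4 tables of annotation terms for genes higher and lower at each time. The tool and gene threshold behind those term tables are not given in the sources used here.

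Whole reads were recovered from the deposited means. Each mean is a sum of 2 whole numbers, 1 per library, each multiplied by a fixed worth per read, and the worths were found from the lowest values. Within a tolerance of 0.65 of the last printed digit, 100% of the values above 0 came out as whole reads in all 4 samples. The whole reads had 1 solution for 99.5% and 98.5% of genes at 75 nM and 750 nM at 12 h, and for 99.1% of genes at each dose at 24 h. The remaining genes have large means, and no SD is given for them. They stayed in the fits with the solution whose 2 libraries agreed best, which makes their spread as small as it can be. They include 29 of the genes called at 12 h and 2 of those called at 24 h in the authors' deposited tables. The reads come from the deposited means, so fits of all libraries share the direction of the deposited folds almost by construction. Off-lattice control values were decoded in at most 0.0377% of cases. This control used lower values only, so it does not speak for genes with large means. On simulated tables the share of genes recovered was from 99.66% to 99.98%. The lowest share was that of the 750 nM sample at 24 h, whose worths per read were nearly equal (0.4977 and 0.4984). In that sample size factors recomputed from the recovered reads differed slightly from the decoded ones (1.00441 against 1.00464 in library a). The libraries of a pair carry no labels and are called a and b. The recovered reads summed to 19888024 and 17616226 at 75 nM and to 21905208 and 20338833 at 750 nM at 12 h. At 24 h they summed to 25786253 and 21942733 at 75 nM and to 23720692 and 23012067 at 750 nM. Per degree of freedom, the chi-square between libraries of a pair was 1.67 at 75 nM and 1.79 at 750 nM at 12 h, and 1.47 at 75 nM and 4.79 at 750 nM at 24 h, so no pair agreed within sampling noise. Between libraries of different doses it was 3.28 to 4.16 at 12 h and 4.58 to 5.66 at 24 h. GEO lists each pair as 1 sample and nothing says that the libraries came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Those of cameraPR, Fisher's exact test and the permutation tests compare genes with one another. No p-value here covers the spread between cultures known to be separate.

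The design was fixed before the data were examined. For tables of this kind it took the authors' deposited adjusted p below 0.05 as the call, counted by direction at each time, and these calls are the main results. The count test was added after the files were seen, because whole reads could be recovered. It was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and filterByExpr on the recovered reads, and it called 769 genes at 12 h and 71 at 24 h among 13026 and 13190 genes kept. The common biological coefficient of variation was 2.28% at 12 h and 3.97% at 24 h. Standard errors of log2 fold changes came from DESeq2 1.42.0 on the same reads. The difference of the dose effect between times was tested as the interaction term of 1 edgeR fit of all 8 libraries, also added later. Adjusted p-values of edgeR and DESeq2 are Benjamini-Hochberg values, and those DESeq2 leaves undefined were kept so and out of counts of lost calls. Because with its independent filtering it gave an adjusted p for only 26 of the 52 deposited calls at 24 h, DESeq2 was also run without that filtering, an addition made last.

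The edgeR step was tested on simulated data drawn from the real means and library sizes, with 200 genes changed. The changed genes all had a mean of at least 100, and every gene and dose had the same common dispersion. At 12 h, over 13044 genes, it recovered 80.9% of genes changed 1.25-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold, and 10 of 196 calls were false. At 24 h, over 13194 genes, the shares were 73.5%, 98.5% and 100%, and 9 of 190 calls were false. The real pairs at 24 h had unequal spread (chi-square per degree of freedom 1.47 at 75 nM and 4.79 at 750 nM). The simulated shares therefore do not give the power or false calls of the real 24 h data, or of genes with few reads.

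Gene lists, 48 in all, were fixed from textbook knowledge before the data were examined and covered signalling, B-cell identity, stress, metal handling, metabolism, cell cycle, antigen presentation and markers of other cell types. Each list with at least 5 measured members was tested with limma 3.58.1 cameraPR on the signed statistic of the deposited p, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members were also counted by their deposited calls and by calls adjusted over the list alone. List medians are over members with a mean of at least 100 normalized reads. As an addition, camera was run on the recovered reads with the preset correlation and with an estimated correlation, and limma's fry beside it. With an estimated correlation camera takes its degrees of freedom from the few libraries instead of the genes, so it has little power. MHC class I presentation at 12 h had an estimated correlation of -0.05, under the preset 0.01. Its camera adjusted p still went from 5.14e-05 to 0.571. Failing with an estimated correlation therefore does not decide about a list. Other passing lists had estimates well above the preset, such as 0.31 for mitosis and G2/M and 0.19 for ribosomal proteins at 12 h. At 24 h the estimates were 0.25 for MYC and ribosome biogenesis, 0.49 for the ATF4 list and 0.57 for proteasome subunits. If members of such lists vary together that much, the preset correlation makes their cameraPR p-values too small. Many genes sit on more than 1 list, so the list tests overlap.

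Genes are named by a rule set before the data were examined. It took, per time, the 10 genes called higher and the 10 called lower with the largest fold among those with a mean of at least 100 and a symbol that is not clone-based. It added up to 4 members with the smallest adjusted p of each list that passed and 8 NF-kB target genes whatever their p. It added up to 5 genes called in the same and 5 in opposite directions at the 2 times, and MYC, BCL2, NFKBIA, TNFAIP3, IRF4, CDKN1A and MKI67 whatever their values. The text gives a selection of these, some single genes are not reported here, and any other gene is said to have been chosen after its values were seen.

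Coordinates and exon lengths come from GENCODE release 29 on GRCh38, to which 21912 of the 25559 symbols were matched by symbol or older synonym. For 135 symbols that fall on the same annotated gene as another symbol of the tables, no sharing value was used. Sharing between copies is the percent of a gene's 31-base subsequences found in another gene. Ratios of genes with few reads carry 95% exact intervals, and a dose at 0 reads was compared with a floor of 3 reads over its pair. These cover counting error only. The alternatives were other p thresholds, a fold limit, an expression limit, centring, other list statistics, DESeq2 size factors, DESeq2's own test, no filter, removal of a gene length trend (lowess span 0.3, prior count 2), removal of genes sharing over 50% of their subsequences, and leaving out each library. No outlier test or count of other sample splits was made, because no group has over 2 libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.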

Results

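The transcriptome of OCI-Ly10, an established line of activated B-cell-type diffuse large B-cell lymphoma, was compared between doses of CU-O75. The series addresses the effect of a compound family on lymphoma cells and its action on NF-kB, a family of transcription factors active in this lymphoma type. The dose labels give 750 nM and 75 nM, which the sample titles call the IC20 and the IC20 divided by 10, at 12 h and 24 h. Every comparison is therefore of 750 nM with 75 nM, each a pair of libraries, and effects common to both doses do not appear in it. The DMSO samples were not analysed here. Recovered reads per library ranged from 17616226 to 25786253.

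At 12 h, metallothionein genes, which encode small metal-binding proteins, had the largest increases at 750 nM among called genes with a mean of at least 100 normalized reads. MT2A rose from 74.2 ± 12.3 to 1664 ± 120 normalized reads (SD, n = 2 libraries per dose), MT1F from 19.6 ± 0.964 to 392 ± 48.8 and MT1X from 69.8 ± 2.90 to 408 ± 24.3. SLC30A1, a zinc exporter of the plasma membrane, rose from 361 ± 21.7 to 833 ± 0.349 (SD, n = 2), and SLC39A10, a zinc importer, fell from 548 ± 35.4 to 227 ± 10.9. In the authors' deposited table these were folds of 22.4, 19.98, 5.84 and 2.31 for the 4 genes that rose, with adjusted p-values of 1.19e-133, 1.33e-40, 6.27e-50 and 2.23e-32. The authors' deposited table gave SLC39A10 a log2 fold change of -1.27 with an adjusted p of 9.26e-24. DESeq2 standard errors of the log2 fold change were 0.15 for MT2A and 0.12 for SLC30A1. MT1H had 2 reads in the 75 nM pair and 466 in the 750 nM pair, a normalized ratio of 207 with a 95% exact interval from 56.9 to 1711. Metallothionein genes are related to one another in sequence, so the split of reads among them is uncertain. On GRCh38 they form a cluster on chromosome 16, with MT2A at 56608199 to 56609497, MT1F at 56657694 to 56660698, MT1H at 56669814 to 56671129 and MT1X at 56682424 to 56684196, all on the plus strand. SLC30A1 lies on chromosome 1 at 211571568 to 211578742 and SLC39A10 on chromosome 2 at 195575977 to 195737702.

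**Figure D1:**
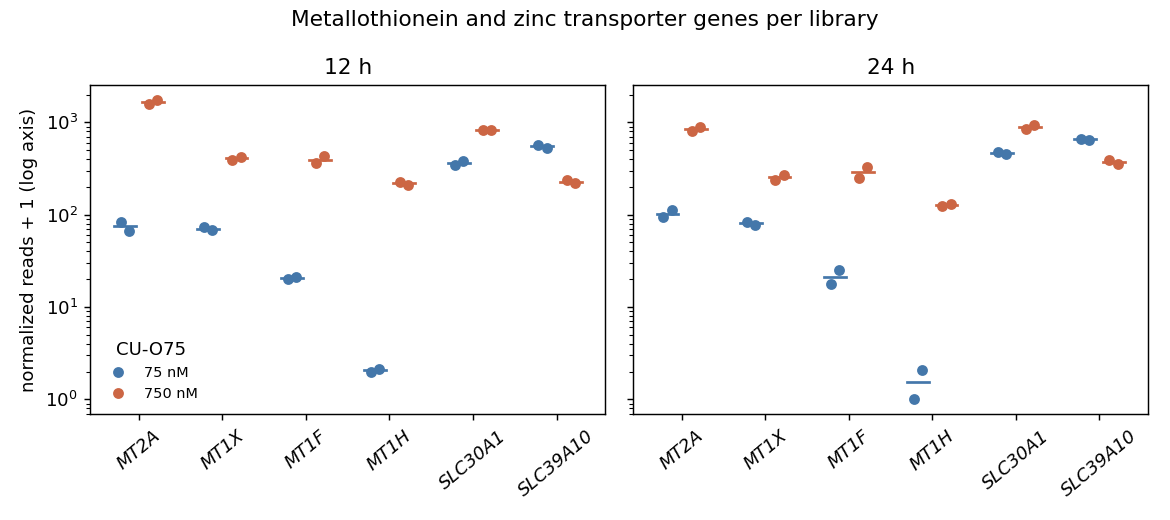
Normalized reads plus 1 (log axis) of metallothionein and zinc transporter genes at 12 h (left) and 24 h (right), with 1 point per library and a bar at the mean of each dose. The 750 nM libraries lie above the 75 nM libraries for MT2A, MT1X, MT1F, MT1H and SLC30A1 and under them for SLC39A10 at both times.

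Of 17968 genes with a p at 12 h, 274 passed an adjusted p of 0.05 in the authors' deposited table, 171 higher and 103 lower at 750 nM. Most changes were small: the median absolute log2 fold change of called genes was 0.26 and 241 of them changed by under 1.5-fold. Metallothioneins were 4 higher, 0 lower and 3 not called of 7 measured, with the same counts adjusted over the list alone (limma cameraPR adjusted p = 8.14e-120). Their median log2 fold change was 4.40. Only 4 members passed filterByExpr, under the minimum of 5, so the list was not tested in camera on the recovered reads or with an estimated correlation. Zinc and copper transporters were 1 higher (SLC30A1), 1 lower (SLC39A10) and 19 not called of 21, and the list did not pass (adjusted p = 0.0542, limma cameraPR).

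Of the lysosome and autophagy genes 9 of 31 were higher, 0 lower and 22 not called (13 higher and 2 lower adjusted over the list alone, median log2 0.10). The list passed limma cameraPR with an adjusted p of 8.11e-13, and camera gave an adjusted p = 0.571 with an estimated correlation. The lysosomal protease CTSD rose by 0.39 on the log2 scale (adjusted p = 3.94e-14), the sialidase NEU1 by 0.34 (4.62e-05) and the galactosidase GLA by 0.30 (0.00212) in the authors' deposited table. Of the NRF2 antioxidant genes 6 of 23 were higher and 0 lower (7 and 0 adjusted over the list alone), with limma cameraPR at 4.51e-12 and camera at an adjusted p = 0.571 with an estimated correlation. The members called were the ferritin subunits FTL (log2 0.35) and FTH1 (0.41), which store iron, GCLC (0.25), of glutathione synthesis, SQSTM1 (0.18), HMOX1 (0.70), which degrades heme, and TALDO1, chosen after its value was seen, all in the authors' deposited table. Iron handling genes were 3 higher of 13, the ferritins and HMOX1 again, and 0 lower (4 and 0 adjusted over the list alone; cameraPR adjusted p = 8.80e-11, and adjusted p = 0.571 with an estimated correlation). HMOX1 lost its call in DESeq2 on the recovered reads (adjusted p = 0.0514, with a range over the fits of those reads from 1.92e-05 to 0.0844). Immediate-early and AP-1 genes were 7 higher and 1 lower of 26 (9 and 1 adjusted over the list alone), with a cameraPR adjusted p of 1.20e-06 and an adjusted p = 0.571 with an estimated correlation. On the recovered reads edgeR called 10 of them and DESeq2 4, with or without independent filtering, while for the lysosome and autophagy genes edgeR called 13 and DESeq2 7, or 6 without it. NR4A3 rose by 0.61 on the log2 scale (3.39e-07) and the phosphatase gene DUSP5 by 0.49 (0.000162) in the authors' deposited table, and the member that fell was MYC (-0.21, 0.000113).

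Of the MHC class I presentation genes 4 of 15 were lower at 12 h, 0 higher and 11 not called (8 lower adjusted over the list alone, median log2 -0.20). The list passed limma cameraPR with an adjusted p of 7.62e-14, and camera gave an adjusted p = 0.571 with an estimated correlation. HLA-B fell from 5380 ± 211 to 3854 ± 115 normalized reads (SD, n = 2). The authors' deposited table gave log2 fold changes of -0.48 for HLA-B (adjusted p = 3.66e-16), -0.40 for HLA-C (1.36e-05) and -0.22 for PSMB10 (0.0290), an immunoproteasome subunit. HLA genes share sequence with one another, and PSMB10 lost its call in DESeq2 on the recovered reads (adjusted p = 0.0884, range over the fits from 0.000532 to 0.144). B-cell identity genes were 3 lower and 0 higher of 20 (6 lower and 1 higher adjusted over the list alone), with a cameraPR adjusted p of 4.42e-06 and an adjusted p = 0.571 with an estimated correlation. These were the coactivator POU2AF1 (log2 -0.22), the tetraspanin CD37 (-0.14) and the transcription factor EBF1 (-0.30) in the authors' deposited table, of which EBF1 lost its call in DESeq2 (adjusted p = 0.143, range over the fits from 0.00185 to 0.233). ATF4 and integrated stress response genes were 3 lower and 0 higher of 30 (5 lower and 0 higher adjusted over the list alone), namely the serine and folate enzymes PHGDH (-0.24), ALDH1L2 (-0.27) and PSAT1 (-0.14) in the authors' deposited table. That list had a cameraPR adjusted p of 6.80e-06 and an adjusted p = 0.571 with an estimated correlation. Ribosomal proteins were 2 lower and 0 higher of 66 (8 and 1 adjusted over the list alone, median -0.06), with a cameraPR adjusted p of 8.11e-13 and an adjusted p = 0.589 with an estimated correlation.

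NF-kB target genes moved both ways at 12 h, 4 higher, 2 lower and 27 not called of 33 (6 higher and 5 lower adjusted over the list alone). Of its members 12 had an unadjusted deposited p under 0.05, and on the recovered reads edgeR called 11 and DESeq2 7, or 5 without independent filtering. The list did not pass (limma cameraPR adjusted p = 0.785), and its median log2 fold change was -0.02 while its mean was 0.04. The chemokine gene CCL4 rose from 57.1 ± 10.2 to 114 ± 2.55 normalized reads (SD, n = 2). Its adjusted p in the authors' deposited table was 0.00496, and it lost its call in DESeq2 with no independent filtering (0.0765, range over the fits from 6.63e-06 to 0.0765). CCL3 rose by 0.99 on the log2 scale (adjusted p = 0.000529) in the authors' deposited table, which also gave increases for the activation marker CD83 (0.28, 6.87e-07) and the chemokine receptor CCR7 (0.28, 0.000699). IRF4, a transcription factor on which this lymphoma type depends, had a log2 fold change of -0.21 (9.15e-07) and TNIP1, a regulator of A20, of -0.15 (0.0294) in the authors' deposited table. TNIP1 lost its call in DESeq2 with no independent filtering (adjusted p = 0.0811) and without 75 nM library a (edgeR adjusted p = 0.117, range over the fits from 0.00165 to 0.117). NFKBIA and TNFAIP3, feedback inhibitors of NF-kB, stood at -0.20 (0.255) and -0.14 (0.320) in the authors' deposited table and were not called there. In edgeR on the recovered reads both were called lower (adjusted p = 0.0113 and 0.0281), with ranges over the fits from 0.000924 to 0.407 and from 0.00663 to 0.455. BCL2 (0.09, 0.270), CDKN1A (0.07, 0.796) and MKI67 (0.03, 1) were not called either in the authors' deposited table.

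Among the other genes with large changes at 12 h, TUBA1B, an alpha-tubulin gene on chromosome 12 at 49127782 to 49131397, rose from 936 ± 54.0 to 2830 ± 204 normalized reads (SD, n = 2). It shares 36.2% of its 31-base subsequences with another gene. BAI1 rose by 0.96 on the log2 scale in the authors' deposited table, and RAPGEFL1 was 2.01-fold higher there, while TXNIP, a thioredoxin-binding protein, stood at -0.81 (adjusted p = 0.000826), RIMS3 at -0.58 and EIF3CL at -1.09. EIF3CL shares 65.5% of its subsequences with another gene, so its value is uncertain. The 12 h tests gave 18 of 47 lists past 0.05, 7 higher and 11 lower. Of the 17 of these that could be tested, 13 passed camera with the preset correlation. With an estimated one 0 passed (adjusted p from 0.571 to 0.589), in a test with little power for so few libraries. The recovered reads were decoded from the deposited means, so edgeR could hardly differ from the deposited signs. Of the 274 deposited calls 29 had several decodings, and the one with the closest libraries was used. Calls by edgeR included all 274 deposited calls at 12 h with the same sign, and 228 of them held when any 1 library was left out.

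At 24 h the same metal-handling genes led the increases at 750 nM among called genes with a mean of at least 100. MT2A rose from 102 ± 12.6 to 852 ± 65.7 normalized reads (SD, n = 2), MT1F from 20.2 ± 5.19 to 289 ± 55.2, MT1X from 79.5 ± 3.37 to 255 ± 22.1 and SLC30A1 from 468 ± 14.3 to 898 ± 67.9. SLC39A10 fell from 652 ± 10.3 to 371 ± 26.4 (SD, n = 2). In the authors' deposited table these were folds of 8.36, 14.3, 3.20 and 1.92 for the genes that rose, with adjusted p-values of 1.49e-73, 3.95e-15, 1.51e-14 and 3.28e-15. The authors' deposited table gave SLC39A10 a log2 fold change of -0.81 (adjusted p = 2.57e-09). MT1H had 1 read in the 75 nM pair and 255 in the 750 nM pair, a ratio of 255 with a 95% exact interval from 45.3 to 10105. Metallothioneins were 4 higher, 0 lower and 1 not called of 5 measured, with the same counts adjusted over the list alone (limma cameraPR adjusted p = 9.73e-115). On the recovered reads edgeR called 4 of them, while DESeq2 with its independent filtering left all 5 undefined and without it called 4. Zinc and copper transporters were 1 higher and 2 lower of 20, the second being SLC39A14 (log2 -0.25, adjusted p = 0.0167), a gene chosen after its value was seen, and the list did not pass (0.989) by limma cameraPR on the authors' deposited table. SLC39A14 lost its call in edgeR (adjusted p = 0.0535, range over the fits of the recovered reads from 3.18e-13 to 0.471).

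Of 18224 genes with a p at 24 h, 52 passed in the authors' deposited table, 36 higher and 16 lower, and 34 of them changed by under 1.5-fold. The share higher among genes changed at 24 h was 69.2% in the authors' deposited table, and edgeR with all libraries called 55 higher and 16 lower. Without 750 nM library a most edgeR calls were lower, in a fit with many more calls whose spread came from the 75 nM pair alone. The direction with most calls was therefore not stable. The 2 libraries of the 750 nM sample at 24 h differed from each other about as much as from the 75 nM libraries (chi-square per degree of freedom 4.79, and 4.58 to 5.66 between the doses). HMOX1 (log2 0.83, adjusted p = 0.0164), FAIM3 (0.80), an Fc receptor for IgM, and CRYM (0.61) were among the genes that rose in the authors' deposited table. TXNIP stood at -1.11 (3.60e-05), HLA-B at -0.37 (4.05e-06), the uracil glycosylase gene UNG at -0.31 (0.0190), MYC at -0.28 (0.00563) and TUBA1B at -0.27 (0.0144) in the authors' deposited table. By edgeR, MYC lost its call without 75 nM library a (adjusted p = 0.218) or b (0.210), TUBA1B without a (0.219) or b (0.289), UNG without a (0.0847) or b (0.178) and HMOX1 without a (0.0965). In DESeq2 with no independent filtering UNG (adjusted p = 0.0559) and HMOX1 (0.141) lost theirs. Over the fits of the recovered reads the adjusted p ranged from 2.73e-13 to 0.218 for MYC, from 9.06e-12 to 0.289 for TUBA1B, from 1.90e-10 to 0.178 for UNG and from 1.48e-06 to 0.141 for HMOX1 (edgeR and DESeq2). None of the 34 NF-kB target genes was called in the authors' deposited table or adjusted over the list alone, and the list did not pass (limma cameraPR adjusted p = 0.240). Of its members 3 had an unadjusted deposited p under 0.05, and on the recovered reads edgeR called 0 and DESeq2 0, with or without independent filtering. TNF stood at -0.49 (adjusted p = 0.301), NFKBIA at -0.15 (1) and TNFAIP3 at -0.07 (1) in the authors' deposited table. Without 1 of the 750 nM libraries, all 3 passed in edgeR, with lowest adjusted p-values of 4.57e-05, 0.000362 and 0.0153 and highest ones over the fits of 0.722, 1 and 1.

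Lists of growth and protein folding genes had lower medians at 24 h, with few members called. MYC and ribosome biogenesis genes were 1 lower (MYC) and 0 higher of 32 (3 lower adjusted over the list alone), with a median log2 of -0.14, a cameraPR adjusted p of 7.02e-21 and an adjusted p = 0.619 with an estimated correlation. Heat shock genes were 0 higher and 0 lower of 20 (7 lower adjusted over the list alone), with a median of -0.17, a cameraPR adjusted p of 2.10e-09 and an adjusted p = 0.619 with an estimated correlation. Of the heat shock genes 9 had an unadjusted deposited p under 0.05, and edgeR called 0 and DESeq2 3, or 2 without independent filtering. DNA replication and G1/S genes were 1 lower (UNG) of 38 (3 lower adjusted over the list alone), with a cameraPR adjusted p of 2.37e-10 and an adjusted p = 0.619 with an estimated correlation. ATF4 and integrated stress response genes had 0 of 30 called over all genes or adjusted over the list alone, 7 with an unadjusted p under 0.05 and 0 called by edgeR or by DESeq2 with or without independent filtering, with a cameraPR adjusted p of 2.03e-09 and an adjusted p = 0.619 with an estimated correlation. The libraries of the 750 nM sample stood apart in these lists. Against the 75 nM pair the G1/S median was -0.04 in library a and -0.16 in library b, and the ATF4 median was -0.20 in a and -0.05 in b. MHC class I presentation was 1 lower (HLA-B) of 15 (2 lower adjusted over the list alone), with a cameraPR adjusted p of 1.06e-05 and an adjusted p = 0.619 with an estimated correlation. Proteasome subunits, tubulins, aminoacyl-tRNA synthetases and splicing factors also passed lower. Of the proteasome subunits 0 of 31 were called over all genes or adjusted over the list alone. Their median was -0.01 in library a and -0.13 in library b, so the shift lay mostly in library b. Of the aminoacyl-tRNA synthetases 0 of 20 were called, and of the tubulins 1 of 12. Splicing factors had 0 of 30 called (1 lower adjusted over the list alone) and a median of -0.10, -0.09 in library a and -0.12 in library b. Their cameraPR adjusted p was 2.37e-12, and camera gave an adjusted p = 0.619 with an estimated correlation. In all 18 of 46 lists passed, 5 higher and 13 lower. Of the 17 of these that could be tested, 14 passed camera with the preset correlation. With an estimated one 0 passed (adjusted p from 0.619 to 0.698), in a test with little power for so few libraries. Proteasome subunits had an estimate of 0.57 and the ATF4 list of 0.49, above the preset, so preset p-values of such lists may be too small. The edgeR count of genes changed at 24 h, 71, became 2518 without 750 nM library a and 1484 without library b, when only the 75 nM pair gave the spread, and 19 of the 52 deposited calls held when any 1 library was left out. With all libraries edgeR called 49 of the 52, with the same sign, which reads decoded from the deposited means could hardly change.

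**Figure D2:**
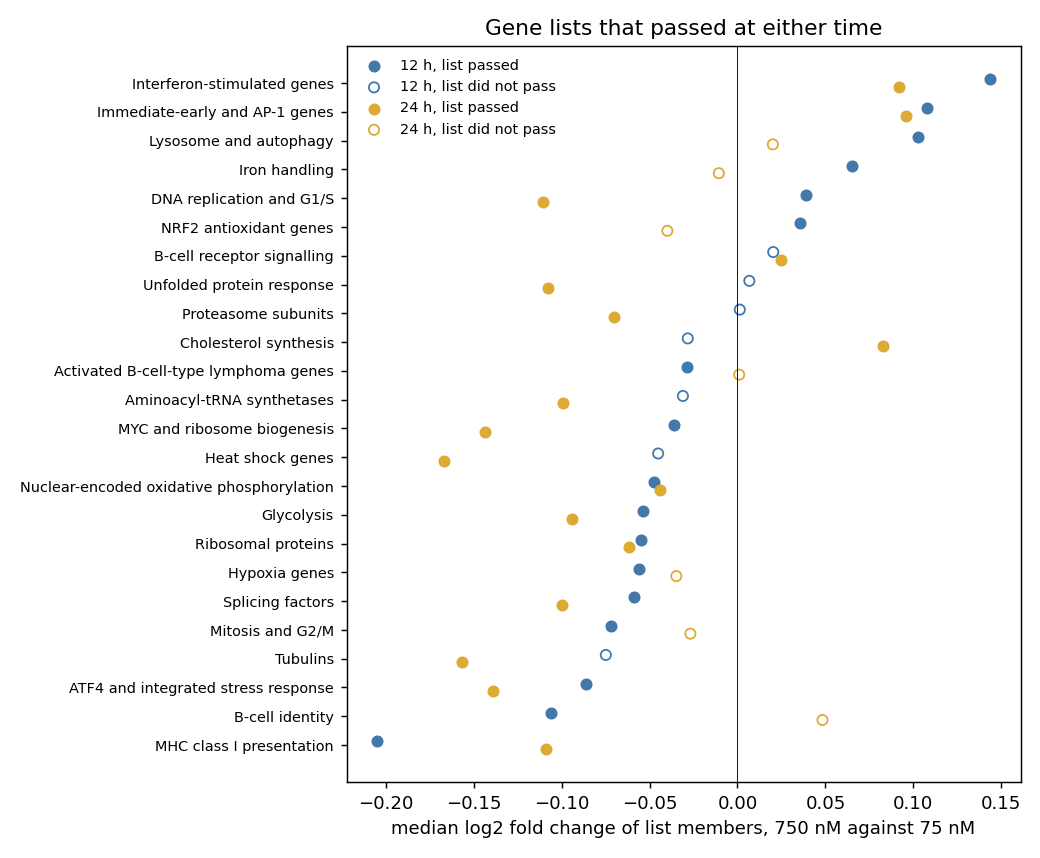
Median log2 fold change (750 nM against 75 nM) of the members of each gene list that passed at either time, with 12 h in blue and 24 h in yellow, filled where the list passed cameraPR. Metallothioneins (4.40 and 3.06) lie off the scale and are not drawn, and all other medians are small, from -0.20 for MHC class I presentation to 0.14 for interferon-stimulated genes, both at 12 h.

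The times were then compared. MT2A, MT1F, MT1X, SLC30A1 and CRYM were called higher at both times, and SLC39A10, TXNIP, HLA-B and MYC lower at both, in the authors' deposited table. In all 22 genes were called at both times among 17265 with a p at both, 15 higher at both, 6 lower at both and 1, TUBA1B, in opposite directions. Independent lists of these sizes would share 0.825 genes, 0.357 higher and 0.0955 lower (Fisher's exact test, two-sided, p = 1.96e-26, with genes not independent replicates). Across 9881 genes with a mean of at least 100 at both times, which are not independent replicates, the log2 fold changes had a Pearson coefficient of 0.507, 0.415 without metallothioneins, and a Spearman coefficient of 0.251. Of the 252 genes called at 12 h and not at 24 h, 203 had the same sign at 24 h.

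The dose effect itself differed between the times for 16 of 13374 genes by the interaction term in edgeR, 7 with a more positive change at 24 h and 9 with a more negative one. Leaving out 1 library moved this count for the interaction of dose and time to between 1 and 766. MT2A rose less at 24 h (difference of the log2 changes -1.40, adjusted p = 0.00713 in edgeR), and TUBA1B turned from higher to lower (difference -1.86, adjusted p = 3.00e-09 in edgeR). SLC30A1 was not among them (adjusted p = 0.389 in edgeR). By camera with the preset correlation 13 of 42 lists differed between the times, and the lowest adjusted p = 0.362 with an estimated correlation. Lysosome and autophagy genes, with 9 called at 12 h and 0 of 31 at 24 h (2 with an unadjusted p under 0.05, 0 by edgeR or by DESeq2 with or without independent filtering), were among the 13 (adjusted p = 0.00463 by camera), as were NRF2 antioxidant genes (0.000262) and B-cell identity genes (0.000266), and each had an adjusted p = 0.362 with an estimated correlation. NF-kB target genes were not (0.484 by camera).

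**Figure D3:**
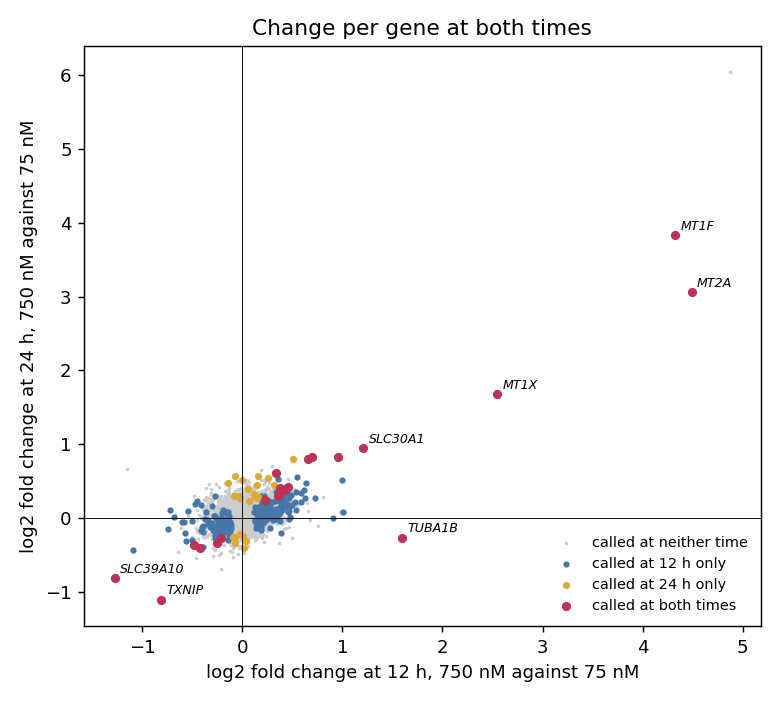
Log2 fold change (750 nM against 75 nM) at 12 h on the horizontal axis and 24 h on the vertical axis, with 1 point per gene with a mean of at least 100 normalized reads at both times and a finite fold. MT1F, MT2A, MT1X and SLC30A1 lie at the upper right, SLC39A10 and TXNIP at the lower left, and TUBA1B at the lower right with 1.60 at 12 h and -0.27 at 24 h. The gray point at the upper right was not called at either time.

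The deposited term tables carried the lysosome genes as well. In the authors' deposited table for terms of genes higher at 12 h, the top term was lysosome with 14 genes and a fold enrichment of 7.17, in a cluster with a score of 6.06, and 25 of 881 terms had a Benjamini value under 0.05. The authors' deposited table for terms of genes lower at 12 h led with cell cycle process (12 genes), and 0 of 477 terms passed. For genes higher at 24 h the authors' deposited table led with regulation of leukocyte activation (5 genes, Benjamini value 0.589), with 0 of 184 terms past the threshold, and for genes lower at 24 h with an RNA recognition motif domain (4 genes, 0.0367), with 1 of 103. All 242, 126, 50 and 26 listed genes found in the full tables had the stated direction there. Their highest adjusted p-values in the authors' deposited tables were 0.248, 0.247, 0.243 and 0.249, so the lists reach beyond the 0.05 threshold used here. These lists were chosen on these samples and are not independent evidence of direction.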

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

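All tests of explanations in this part were chosen after the result was seen. Those on gene length had their criteria written before their own outcome, but they rest on recovered reads, so the data had been seen by then. The interaction test was run after whole reads had been recovered.

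The change with dose differed between 24 h and 12 h for 16 genes by the edgeR interaction term, each drawn out because the difference itself passed an adjusted p of 0.05. Values are the 24 h log2 change minus the 12 h one, and these genes were chosen after their values were seen apart from TUBA1B, MT2A, MX1, NFATC1 and EBF1. TUBA1B differed by -1.86 (adjusted p = 3.00e-09 in edgeR) and MT2A by -1.40 (0.00713 in edgeR). PDCD1, the PD-1 receptor gene, differed by -0.42 (0.00560), CD1C, which presents lipids, by -0.59 (0.00759), the desaturase gene FADS2 by 0.57 (0.00560), all in edgeR. The interferon-induced MX1 differed by -0.48, PRNP by -0.41, DTX4 by -0.38, the small heat shock gene HSPB1 by -0.36 and NFATC1 by -0.31. Positive differences were 0.67 for RNF144B, 0.61 for COL4A5, 0.59 for RASSF4, 0.46 for EBF1, 0.38 for DMXL1 and 0.33 for SNX29. For MX1, PRNP, DTX4, HSPB1, NFATC1, EBF1, DMXL1, COL4A5, RASSF4, SNX29 and RNF144B the adjusted p lay between 0.0334 and 0.0483 in edgeR. At an unadjusted p under 0.05 there were 1368 genes, and DESeq2 called 29, 11 of them among the 16, for 12 of which it gave an adjusted p. The interaction of dose and time depended on single libraries, with 1 and 3 genes without 75 nM library a and b at 12 h, 6 without either 750 nM library at 12 h and 2 without either 75 nM library at 24 h. It gave 766 without 750 nM library a at 24 h and 158 without b.

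Among called genes with a mean of at least 100, the largest changes were those of metallothionein transcripts. Reads moving between related metallothionein genes would leave their sum level. The sum over all 15 metallothionein genes was at least 6.66 times higher in any 750 nM library than in any 75 nM library. That held at both times, which argues against such a move of reads. A heat shock response would raise the heat shock list. Among its members with a mean of at least 100, the upper quartile of log2 changes was 0.00463 at 12 h and -0.131 at 24 h. This argues against a broad heat shock response at these times. At 12 h, however, 1 of its 20 members was called higher and 2 lower. HSPB1, chosen after its value was seen, rose by 0.19 at 12 h (adjusted p = 0.000877 in the authors' deposited table). Times before 12 h were not sampled, so an earlier response was not tested. An NRF2 oxidative stress response stays open, since the upper quartile of that list reached 0.235 at 12 h while its median was 0.04 at 12 h and -0.04 at 24 h. At 12 h 6 of its 23 members were called higher, of which FTL, FTH1 and HMOX1 are also on the iron list. Its members NQO1 (adjusted p = 0.810 at 12 h), GCLM, TXNRD1 and SRXN1, chosen after their values were seen, were not called at either time in the authors' deposited table. A change in available metal ions in the cells at 750 nM, which SLC30A1 and SLC39A10 may also follow, is a hypothesis that no value here tests, and the dose itself also stays open.

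For large changes in genes with near-identical copies, called genes with an absolute log2 change of at least 1, metallothioneins left out, shared a median of 0.267% of their subsequences with another gene against 0.128% for other called genes (15 against 277 genes, permutation test, one-sided, p = 0.399). The mean, a second statistic tried, was 24.9% against 5.74% (permutation test, one-sided, p = 0.000470), so the 2 statistics disagree. The criterion written for the median, a p of 0.05 or more, would have argued against shared reads, and calling them open was settled after both had been seen. Of the 15 genes 6 shared over 30% and 9 under 2%, while 16 of the 277 other called genes shared over 30%. The median falls among the genes with little sharing, so it cannot show such an excess. For TUBA1B at 12 h, reads moved between TUBA1A, TUBA1B and TUBA1C would leave their sum level, but the sum was 1.28 times higher at 750 nM and at least 1.22 times for every pair of libraries, which argues against this as the whole cause. At 75 nM the sum was 5762 and 5566 in the libraries at 12 h but 11156 and 11117 at 24 h, each time scaled separately. At 750 nM it was 7012 and 7521 at 12 h and 9540 and 9821 at 24 h. Whether the 12 h change reflects a low sum at 75 nM at that time was not tested.

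At 24 h longer genes tended to be higher at 750 nM, with a Spearman coefficient across 9511 genes of 0.203 between exon length and the log2 change, genes not being independent replicates. Between the libraries of the 750 nM sample the coefficient was -0.0181 and between those of the 75 nM sample -0.0208, which argues against a length trend that varies from library to library. At 12 h, however, the coefficient between the 750 nM libraries was 0.125, above that of the dose contrast, 0.0733. A length trend common to both libraries of a sample was not excluded, because each dose at each time is 1 sample. Of 64 edgeR calls at 24 h outside the metallothionein and zinc transporter genes, 52 (81.3%) held after the length trend was removed, which argues against the trend as the whole cause of those calls, and no biological explanation was tested.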

How the results depend on the processing

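All fits on recovered reads were chosen after the data were seen, including the estimated correlation, and the p thresholds, fold and expression limits, centring and list settings before. No paired analysis was possible because the columns carry no replicate numbers. The 274 genes changed at 12 h were 177 at an adjusted p of 0.01, 15 with an absolute log2 change of at least 1, and 769 with edgeR, 775 with DESeq2 size factors in edgeR, 947 with no filter and 806 with the length trend removed. Leaving out each library gave 513 to 791 in edgeR. The 52 genes changed at 24 h were 25 at 0.01, 11 with the fold limit and 22 in edgeR with no filter, and 58 to 2518 in edgeR leaving out each library, the upper end without 750 nM library a (1484 without b), where the spread comes from the 75 nM pair alone. Other settings stayed within 1.5 times, though the share of calls higher at 24 h, 69.2%, was 58.9% in DESeq2 and 40.1% without 750 nM library a. Passing gene lists at 12 h, 18, were 3 with the log2 change as statistic and 0 with an estimated correlation, and gene lists at 24 h, also 18, were 1 and 0. The estimated correlation leaves little power with so few libraries. By fry on the recovered reads MHC class I presentation passed at 12 h (adjusted p = 0.0451) and 24 h (0.0361). Anti-apoptotic genes, which did not pass cameraPR, passed fry at 24 h (0.00205), and no other list passed fry at either time. Genes called alike in 12 h against 24 h, 21, were 4 with the fold limit at both times and 33 with edgeR. The interaction of dose and time, 16 genes, gave 29 in DESeq2 and 1 to 766 leaving out each library. The cause was not tested, beyond fewer libraries or a stricter limit where these define the setting. A lone library was assumed to vary like the others.

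No call of a named gene turned direction. Most edgeR calls at 24 h were lower instead of higher without 750 nM library a. In that fit the spread came from the 75 nM pair alone and calls rose in both directions, more so the lower ones. Over 191 pairs of a named gene and a time, fits of the recovered reads kept 1342 values on their side of the threshold, 302 passed it newly and 46 no longer passed. Centring moves no p and is left out of these. DESeq2 called 213 of 269 deposited calls with a defined value at 12 h and 26 of 26 at 24 h. Without independent filtering it called 194 of 274 and 38 of 52. Depth limits genes with few reads, such as MT1H at 75 nM, whose ratios have wide intervals.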

Other observations

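No test of an explanation is reported in this part, and genes named here other than MX1 and BMF were chosen after their values were seen. Interferon-stimulated genes were 2 higher, 0 lower and 29 not called of 31 at 12 h (6 higher and 3 lower adjusted over the list alone), with a cameraPR adjusted p of 0.000313 and an adjusted p = 0.571 with an estimated correlation. MX1 rose by 0.46 on the log2 scale (adjusted p = 0.00212) in the authors' deposited table. The checkpoint genes PDCD1 and CD274, which encode PD-1 and its ligand, rose at 12 h by 0.38 (2.49e-16) and 0.48 (1.22e-05) in the authors' deposited table, and at 24 h stood at -0.04 and 0.01, both with an adjusted p of 1. The difference between times passed for PDCD1 (adjusted p = 0.00560 in edgeR) and not for CD274 (0.0803 in edgeR).

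DNA replication and G1/S genes had a median log2 change of 0.04 at 12 h (cameraPR adjusted p = 0.00125, and adjusted p = 0.589 with an estimated correlation) and of -0.11 at 24 h, -0.04 in library a and -0.16 in library b. At 12 h 0 of 38 were called in the authors' deposited table or adjusted over the list alone, 8 with an unadjusted p under 0.05, 4 by edgeR and 0 by DESeq2 with or without independent filtering. The difference between times had an adjusted p of 9.35e-08 by camera, and an adjusted p = 0.362 with an estimated correlation. Mitosis and G2/M genes had a median of -0.07 at 12 h with 0 of 32 called in the authors' deposited table, 7 with an unadjusted p under 0.05, 3 called by edgeR and 1 by DESeq2 (cameraPR adjusted p = 7.01e-06, and adjusted p = 0.589 with an estimated correlation). At 24 h unfolded protein response genes had a median of -0.11 with 0 of 22 called, 10 with an unadjusted p under 0.05, 5 lower adjusted over the list alone and 0 by edgeR or by DESeq2 with or without independent filtering (cameraPR adjusted p = 1.91e-09, and adjusted p = 0.619 with an estimated correlation). Cholesterol synthesis genes had a median of 0.08 at 24 h, 0.01 in library a and 0.14 in library b, with 0 of 23 called over all genes or adjusted over the list alone, 3 with an unadjusted p under 0.05 and 0 by edgeR or by DESeq2 with or without independent filtering (cameraPR adjusted p = 0.000346, and adjusted p = 0.698 with an estimated correlation). The p53 target list had 0 of 23 called at 12 h and 0 of 25 at 24 h (1 adjusted over the list alone), with 1 and 3 at an unadjusted p under 0.05 and 0 and 1 by edgeR as by DESeq2, and did not pass (cameraPR adjusted p = 0.928 and 0.0611). Among pro-apoptotic genes BIK was higher and BMF lower at 12 h of 22 measured, and the list did not pass (0.732 by cameraPR).

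Markers of other cell types gave few calls, and no such list passed by cameraPR at either time. The stromal, endothelial and epithelial list was among those that differed between the times by camera with the preset correlation (adjusted p = 0.0427). With an estimated correlation its adjusted p was 0.362. At 12 h PRF1 of the NK-cell list rose by 0.45 on the log2 scale (adjusted p = 4.31e-07 in the authors' deposited table). Its normalized reads were 888 ± 40.8 at 75 nM and 1211 ± 23.1 at 750 nM (SD, n = 2). COL1A2 of the stromal list rose at 24 h by 1.51 (2.35e-05 in the authors' deposited table). Its reads were 55 and 35 at 75 nM and 132 and 121 at 750 nM.

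Some genes were erratic within a sample. GRAPL was called at 12 h in the authors' deposited table (adjusted p = 1.16e-17). It had 1 and 5 reads at 75 nM and 81 and 89 at 750 nM at 12 h, and 121, 118, 128 and 0 reads in the same order at 24 h. Only its 750 nM pair at 24 h was erratic, and it shares 32.9% of its subsequences with another gene. EIF3C, not called in the authors' deposited table, had 632 and 1134 reads at 75 nM and 633 and 297 at 750 nM at 12 h. LOC100291786, also not called, had 15 and 0 reads at 75 nM and 0 and 449 at 750 nM at 12 h.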
